A study of Mus musculus with 71 samples.

How the data were processed

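Mouse embryos of 8 genotypes at the miR-17~92 locus were each dissected into tail bud, heart and the rest of the embryo, and the RNA of each part was sequenced. The labels give C57BL/6 embryos at embryonic day 9.5 with 20 to 22 somites, RNA extracted in TRIZOL, TruSeq chemistry and single reads of 50 bases. How the RNA was selected and whether the libraries kept strand were not given in the sources used here. Each genotype and tissue had 3 libraries that the series text calls biological triplicates, except the rest of the embryo of Δ17,18,92, which had 2, for 71 libraries in 24 groups. Groups and replicate numbers were taken from the sample titles. The deposited values are whole-number read counts per gene, not normalised, in 1 table of 37620 genes identified by Ensembl gene IDs. Per the submitters' processing notes, the tools were STAR 2.3.0, SAMtools 0.1.14 and featureCounts of Subread 1.4.2, with the mm9 and NCBIM37 builds. The annotation release, the handling of multi-mapping reads and the strand setting were not given, so reads of overlapping, antisense and near-identical genes could not be told apart with certainty.

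Gene symbols came from the GENCODE annotation of the later GRCm38 build by gene ID, which matched 32897 of the 37620 IDs. Genes without a symbol stayed in all tests and held 0.839% of the counts. The same annotation supplied 3′ untranslated regions (the longest per gene, for 19803 genes in the table) and the order of genes along chromosome 14. Of the 37620 genes, 5496 had no count in any library, and all 37 mitochondrial genes were listed at 0. Library totals ran from 13532012 to 27477273 counts. Every one of the 70 pairs of replicates within a group differed by more than counting noise (lowest chi-square per degree of freedom 2.66, median 9.30), so each was counted as its own sample.

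For each tissue, all of its libraries were fitted together with edgeR 4.0.16 (R 4.3.3): filterByExpr by genotype, TMM factors, robust quasi-likelihood fits and Benjamini-Hochberg adjustment with a threshold of 0.05. The 7 mutant genotypes were compared with wild type in that fit, which tested 17009 genes in tail bud, 16750 in heart and 17512 in the rest of the embryo. A second model coded each library by the seed families its genotype lacks and estimated 4 additive terms, for miR-17 (with miR-20a), miR-18, miR-19 and miR-92. A test of 3 degrees of freedom compared this model with 1 mean per genotype and measured departure from additivity. The 9 wild-type libraries were fitted together to compare tissues, and the 18 wild-type and full knockout libraries to test whether the knockout's effect differed between tissues. DESeq2 1.42.0 served as an alternative tool. Log2 fold changes are given ± SE, and expression levels (CPM, computed here from the deposited counts and TMM factors) as mean ± SD with n = 3 unless stated.

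Seed matches were searched in the 3′ untranslated regions as 8mers and 7mer-m8 sites against bases 2 to 8 of each family's seed. The set score of a library was the mean log2 CPM (prior count 2) of genes with an 8mer match of that family, whatever other matches they hold, minus that of genes without a match of any of the 4 families. It was regressed on the same 4 terms with 100000 permutations of the libraries (two-sided, Benjamini-Hochberg over 48 tests; the smallest p the permutations can give is 1e-05). Camera (limma 3.58.1, preset inter-gene correlation 0.01) tested the 4 seed-match sets in the 21 comparisons with wild type (84 tests) and 16 fixed gene lists in the full knockout (48 tests), and was repeated with an estimated correlation. The lists were reported miR-17~92 targets, Hox genes, tail bud and segmentation, cardiomyocyte, second heart field and pharyngeal mesoderm, endothelium and endocardium, primitive erythroid cells, visceral endoderm and yolk sac, neural progenitors and neurons, somite derivatives, neural crest, p53 targets, cell cycle and E2F targets, hypoxia and glycolysis, TGF-β and BMP signalling, and immediate early and stress genes. A locus list (Mir17hg, Gpc5, Gpc6 and Mcm7) and a sex-linked list were described without a set test. The target list was drawn from general knowledge of the cluster; 10 of its 24 genes are also in other lists and 20 hold a site of at least 1 family.

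Genes were named by a fixed rule. Mir17hg, Bcl2l11 and Cdkn1a were among the genes always named. In the full knockout, up to 10 genes per direction were named by largest fold change, among those past the threshold with mean log2 CPM of at least 2 and every mutant library beyond every wild-type library. The other genotypes contributed up to 2 per direction by the same rule. Each family term contributed up to 4 genes that rose and hold an 8mer and up to 2 that fell, by smallest p. Departure from additivity contributed 3 per tissue, wild-type tissues 4 per direction with mean log2 CPM of at least 5, the tissue interaction 6, and each list up to 4 members past the threshold or, where none passed, up to 2 by smallest p. Genes without a proper symbol and sex-linked genes were counted but not ranked. Some genes that the rule names are not reported here and stay in the counts.

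The comparisons, lists, gene rule and all alternatives except leaving out each library in the additive model and in its seed-match scores were chosen before the data were examined. The tests of lists in genotypes other than the full knockout and several tests of explanations were chosen later. The alternatives were DESeq2, DESeq2 size factors, no filter on low counts, only the groups compared, sex (expression of Y-linked genes) as a covariate, the replicate number as a block, leaving out each replicate, leaving out the full knockout libraries, other site definitions, untranslated regions of 500 to 3000 bases, mean log2 CPM of at least 3, medians in place of means, and fry or an estimated correlation in place of camera's preset. The main tissue fits did not pair same-numbered samples, though the data point to such pairs. The deviations of same-numbered wild-type samples from their group means (10265 genes) correlated above 0.1 in 3 of 3 pairs for tail bud and rest (lowest 0.131) and in 3 of 3 for heart and rest (lowest 0.138). Expression of Y-linked genes matched across tissues in 24 of 24 combinations of genotype and number. In folds against a tissue with 1 to 3 counts in total, the ratio of counts is given with an exact 95% interval, which covers counting error only.

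On counts simulated from the fitted means with 200 changed genes, the tail bud comparison of full knockout with wild type (17009 genes) recovered 87% of 1.5-fold and 100% of 2-fold changes, with 16 of 203 calls (7.88%) on unchanged genes. The miR-92 term in tail bud recovered 74% of 1.2-fold and 96% of 1.5-fold changes, the wild-type heart against tail bud comparison 78% of 1.5-fold and 100% of 2-fold changes, and the tissue interaction 62% of 1.5-fold and 98% of 2-fold changes. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9 were used for tables and figures.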

Results

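The series asked how the members of miR-17~92, a microRNA cluster processed from 1 primary transcript, contribute to gene expression in the mouse embryo. RNA was sequenced from tail bud, heart and the remaining embryo in wild type and 7 mutant genotypes. The full knockout lacks the whole cluster, which holds 6 hairpins of 4 seed families. Δ17 lacks miR-17 and miR-20a, Δ18 lacks miR-18a, Δ19 lacks miR-19a and miR-19b-1, and Δ92 lacks miR-92a-1. The alleles Δ17,18 and Δ17,18,92 combine these losses. Each of the 24 groups held 3 libraries, except the rest of the embryo of Δ17,18,92 with 2. The spread between replicates corresponded to a biological coefficient of variation of 8.74% in tail bud, 8.87% in heart and 6.47% in the rest of the embryo.

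The host transcript of the cluster, Mir17hg (ENSMUSG00000089726, chromosome 14), was higher in most mutants than in wild type. In wild type it stood at 128.2 ± 16.1 CPM in tail bud, 39.75 ± 2.09 in heart and 157.8 ± 3.44 in the rest of the embryo (SD, n = 3). In the full knockout it rose 2.79-fold in tail bud (log2 fold change 1.48 ± 0.07, edgeR adjusted p = 5.47e-13), 3.57-fold in heart (1.83 ± 0.08, adjusted p = 1.09e-13) and 2.80-fold in the rest of the embryo (1.48 ± 0.05, adjusted p = 3.87e-17). Δ17,18,92 raised it by 1.71, 1.75 and 1.58 in the same order of tissues, Δ17 by 0.92, 0.96 and 0.94, Δ17,18 by 1.01, 0.93 and 0.89, and Δ19 by 0.47, 0.48 and 0.61. In Δ92 it rose in tail bud (0.39, adjusted p = 0.00662) and in the rest of the embryo (0.40, adjusted p = 5.14e-05), with 0.33 in heart (adjusted p = 0.281). Δ18 gave 0.09, −0.10 and 0.04, none past the threshold, and the tail bud value turned to −0.0017 without wild-type replicate 3. The tail bud call of Δ92 ended without its own replicate 3 (adjusted p = 0.0655), and those of Δ19 and Δ92 ended when only the 6 libraries compared were fitted. The 6 hairpin genes were listed at 0 in all 71 libraries, and where in Mir17hg its counts lie relative to the deletions is not in the table, so its level checks no label. Of the other genes fixed for the locus, the neighbour Gpc6, a glypican, rose in the full knockout by 0.37 ± 0.06 in tail bud (adjusted p = 7.89e-05), 0.40 ± 0.09 in heart (0.0137) and 0.20 ± 0.05 in the rest of the embryo (0.0073). Gpc5 stood at 0.97 ± 0.51 in tail bud (adjusted p = 0.227), and Mcm7, host of a related cluster on another chromosome, stayed at or under 0.11 in the 3 tissues.

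**Figure D1:**
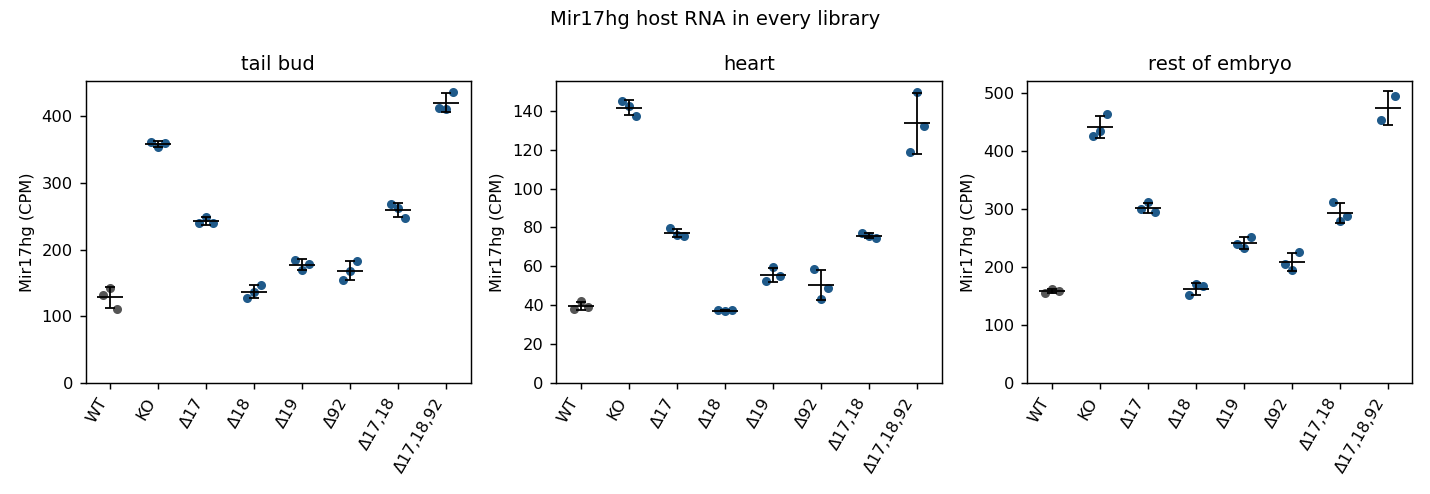
CPM of the host transcript Mir17hg in every library, by genotype and tissue, with group means and SD. Full knockout means are 358.5, 141.8 and 441.1 CPM in tail bud, heart and rest, above the wild type in each.

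In the full knockout tail bud, the largest increases were in Mylip (1.48 ± 0.11, adjusted p = 2.12e-08), a ubiquitin ligase that degrades the LDL receptor, and Reep3 (1.05 ± 0.06, 7.10e-11), which shapes the endoplasmic reticulum. The fibronectin type III domain gene Fndc3b followed (1.04 ± 0.08, 1.45e-08). F3, the tissue factor that starts coagulation, rose by 1.03 ± 0.17 (adjusted p = 0.000217) and the copper transporter gene Atp7a by 0.88 ± 0.06 (1.34e-09). Astn1, which acts in neuronal migration, rose by 0.88 ± 0.14 (0.000203), the protease gene Adamts19 by 0.91 ± 0.11 (4.55e-06), Lonrf1 by 0.92 ± 0.13 (3.10e-05) and the meiotic recombinase gene Dmc1 by 0.92 ± 0.23 (0.0129). The largest decreases were in Gprin1 (−1.02 ± 0.21, 0.0021), Mapk8ip2, a scaffold of JNK signalling (−0.80 ± 0.15, 0.0015), Fbxo6 (−0.76 ± 0.17, 0.00685), the limb and lung growth factor Fgf10 (−0.74 ± 0.17, 0.00703) and the acetyl-CoA synthetase gene Acss2 (−0.73 ± 0.17, 0.00742). Wfikkn1, which binds myostatin and GDF11, fell by 0.68 ± 0.08 (adjusted p = 1.73e-06), Tmem121 by 0.68 ± 0.19 (0.0204), the EGR corepressor gene Nab2 by 0.61 ± 0.18 (0.0272), Carmil3 by 0.61 ± 0.16 (0.0142) and the glutaredoxin gene Glrx by 0.61 ± 0.14 (0.00804). The naming rule required all 3 knockout libraries to lie beyond all 3 wild-type libraries in each of these genes.

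In total 1776 of 17009 tested genes changed in the knockout tail bud, 1008 higher and 768 lower, with a median absolute log2 fold change of 0.31. The count became 771 without wild-type replicate 3, 2839 without wild-type replicate 2, 1083, 1040 and 758 without knockout replicates 1, 2 and 3, and 198 when only these 6 libraries were fitted. Tail bud wild-type replicate 3 stood apart from the others in heart-muscle RNA (Myh6 at 5.36 CPM against 0.514 and 1.17) and in the means of 3 lists, by 0.57 for cardiomyocyte, 0.58 for somite and 0.59 for neural genes. Without that library the calls of Hoxb4 (adjusted p = 0.255), Tbx20 (0.239), Tmem121 (0.213), Hoxa6 (0.188), Dll3 (0.179), Cldn5 (0.173), Nab2 (0.169), Tbx6 (0.153), Mcm3 (0.0967), Glrx (0.0927), Fgf10 (0.0552) and Fbxo6 (0.0549) ended. Those of Mef2c (0.162) and Carmil3 (0.0712) ended without knockout replicate 1, those of Smad7 (0.114) and Tubb3 (0.0632) without replicate 2, and those of Dll1 (0.0955), Acss2 (0.0610) and Dmc1 (0.0514) without replicate 3. Of the 43 genes named in this comparison by the rule and past the threshold, 24 kept their call in every fit that left out 1 library. With only these 6 libraries fitted 19 of the 43 kept it, and of the 24 the calls of F3 (0.0503), Hif1a (0.0509), Hoxb5 (0.0595), Hoxa5 (0.0709), Bcl2l11 (0.0744), Gprin1 (0.0860) and Mcm5 (0.166) ended.

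In the full knockout heart the largest increases after Mir17hg were in Pmepa1, an inhibitor induced by TGF-β (1.21 ± 0.17, adjusted p = 0.000127), the sugar transporter family gene Slc35d3 (1.18 ± 0.20, 0.000752) and the muscarinic receptor gene Chrm2 (1.00 ± 0.24, 0.0230). Clip4, a microtubule-binding family member, followed (0.97 ± 0.09, 5.80e-07). The polysialyltransferase gene St8sia2 rose by 0.94 ± 0.13 (6.45e-05), the kinesin gene Kif1a by 0.94 ± 0.19 (0.00379), Mylip by 0.88 ± 0.12 (3.89e-05), the zinc finger gene Zbtb20 by 0.87 ± 0.14 (0.00176) and the cadherin gene Cdh6 by 0.82 ± 0.18 (0.0103). Among the largest decreases were those of the amine oxidase Aoc3 (−1.01 ± 0.19, 0.00341), the sodium channel subunit Scn4b (−0.88 ± 0.16, 0.00341) and the serotonin transporter Slc6a4 (−0.73 ± 0.15, 0.00462). Zfp641 fell by 0.79 ± 0.19 (0.0145), the matrilin gene Matn3 by 0.70 ± 0.18 (0.0268) and the PAF acetylhydrolase gene Pla2g7 by 0.69 ± 0.15 (0.00736). Prkcb, a protein kinase C, fell by 0.68 ± 0.18 (0.0338), Soat2, which esterifies cholesterol, by 0.66 ± 0.16 (0.0178) and Gimap4 by 0.65 ± 0.15 (0.0109). In total 655 of 16750 tested genes changed, 438 higher and 217 lower, with a median absolute log2 fold change of 0.31.

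The heart count fell to 303, 366 and 350 without wild-type replicates 1, 2 and 3 and to 260 and 368 without knockout replicates 2 and 3, and it was 1010 when only the 6 libraries were fitted. Without wild-type replicate 1 the calls of Pecam1 (adjusted p = 0.163), Soat2 (0.150), Bmpr2 (0.134) and Tgfbr2 (0.114) ended, without replicate 2 those of Matn3 (0.146) and Csrp3 (0.0916), and without replicate 3 those of Prkcb (0.177), Zfp641 (0.0925) and Pla2g7 (0.0523). Without knockout replicate 2 the calls of Zbtb4 (0.162), Chrm2 (0.110), Gimap4 (0.0974), Cdh6 (0.0853) and Mcm5 (0.0703) ended, and without replicate 3 that of Tbx5 (0.130). The other 17 of the 32 named genes past the threshold kept their call in every such fit.

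In the rest of the full knockout embryo, Mylip rose by 1.08 ± 0.08 (adjusted p = 7.21e-11), Reep3 by 0.89 ± 0.05 (1.84e-14) and Fndc3b by 0.88 ± 0.04 (1.44e-15). F3 rose by 0.87 ± 0.12 (6.10e-06), the RING finger gene Rnf11 by 0.83 ± 0.06 (4.65e-11) and Lonrf1 by 0.81 ± 0.08 (7.95e-08). The β-globin gene Hbb-bs rose by 1.18 ± 0.25 (0.00451), though its reads may be shared with Hbb-bt, the metallothionein gene Mt1 by 0.98 ± 0.22 (0.0117) and the transcription factor gene Tcfl5 by 0.88 ± 0.12 (8.55e-06). The largest decreases were in Tmem56 (−1.13 ± 0.17, 7.10e-05), the synaptic scaffold gene Ppfia3 (−0.74 ± 0.16, 0.00236), the adhesion receptor gene Adgrg3 (−0.71 ± 0.15, 0.00185) and Abcc9, which encodes a subunit of the ATP-sensitive potassium channel (−0.69 ± 0.12, 0.00032). The clathrin light chain gene Cltb fell by 0.69 ± 0.11 (0.000145), the clock gene Per2 by 0.64 ± 0.13 (0.000913) and the adenylyl cyclase gene Adcy5 by 0.64 ± 0.14 (0.0024). The glutamine transporter gene Slc38a5 fell by 0.58 ± 0.15 (0.0113), Syt9, a synaptotagmin, by 0.58 ± 0.15 (0.0117) and AW551984 by 0.55 ± 0.12 (0.00465). In total 1167 of 17512 tested genes changed, 809 higher and 358 lower, with a median absolute log2 fold change of 0.26. Of the 34 named genes past the threshold 25 kept their call without any 1 library. The calls of Nkx1-2 (adjusted p = 0.226) and Meox2 (0.174) ended without knockout replicate 1, that of Syt9 (0.0907) without replicate 2, and those of Mcm5 (0.137) and Pecam1 (0.0581) without replicate 3. Among the wild-type libraries, leaving out replicate 1 ended the call of Tfap2b (0.235), replicate 2 that of Slc38a5 (0.0948) and replicate 3 those of Mt1 (0.0621) and AW551984 (0.0556). Mt1 also lost its call with only the 6 libraries (0.222).

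**Figure D2:**
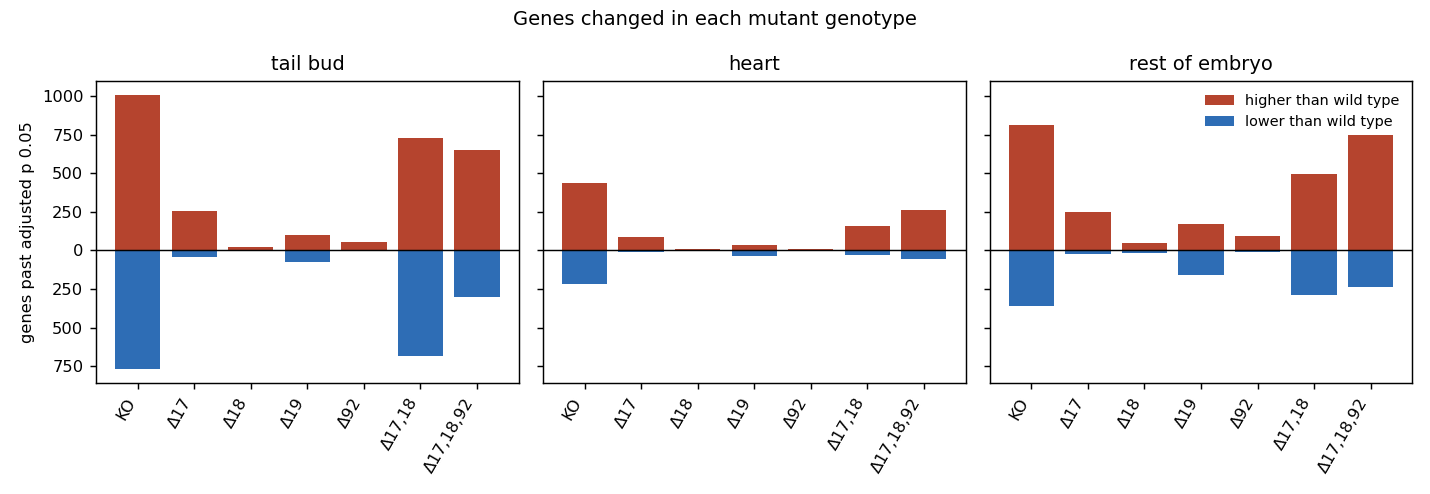
Number of genes past an adjusted p of 0.05 in each mutant genotype against wild type, by tissue, with higher genes above and lower genes below the zero line. The full knockout changed 1776 genes in tail bud, 655 in heart and 1167 in the rest, and Δ18 22, 7 and 63.

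Reported targets of the cluster rose as a group in all 3 tissues of the full knockout (camera, preset correlation, Benjamini-Hochberg over 48 tests). Chance was not excluded for the count of shifted lists. In tail bud 10 of 24 rose and 0 fell (13 and 1 adjusted over the list alone), with median 0.27 and adjusted p = 8.89e-09 (0.00326 with an estimated correlation). In heart 6 rose and Ccnd2 fell (8 and 1 adjusted over the list alone; median 0.15, adjusted p = 5.97e-05, and 0.0328 as the adjusted p with an estimated correlation). In the rest of the embryo 10 rose and 0 fell (13 and 0 adjusted over the list alone; median 0.26, 5.35e-11 and 0.00599). E2f1, a cell cycle transcription factor, rose by 0.37 ± 0.06, 0.35 ± 0.06 and 0.33 ± 0.05 in tail bud, heart and rest of the embryo (adjusted p = 0.000339, 0.000351 and 1.16e-05). The integrin gene Itga5 rose by 0.33 ± 0.04 in tail bud and 0.34 ± 0.05 in the rest of the embryo, and the hypoxia factor gene Hif1a by 0.27 ± 0.05 in tail bud. The zinc finger gene Zbtb4 rose by 0.32 ± 0.08 in heart (0.0155) and Ccn2, a matricellular growth regulator, by 0.68 ± 0.09 in the rest of the embryo. The proapoptotic gene Bcl2l11 rose in tail bud (0.29 ± 0.05, 0.000618), and stood at 0.31 ± 0.09 in heart (0.0626) and 0.15 ± 0.05 in the rest of the embryo (0.0728). The cell cycle inhibitor gene Cdkn1a did not pass in tail bud (0.37 ± 0.17, 0.158), heart (0.02 ± 0.25, 0.982) or the rest of the embryo (0.31 ± 0.11, 0.0832). In fits that left out 1 library its heart value fell as low as −0.0947.

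Genes of TGF-β and BMP signalling rose as a group in all 3 tissues, with 3 of 15 higher in tail bud (5 adjusted over the list alone; median 0.25, adjusted p = 0.00305), 3 in heart (4; 0.14, 0.00462) and 5 in the rest of the embryo (8; 0.19, 2.53e-07), and 0 lower. With an estimated correlation the adjusted p values were 0.0328, 0.305 and 0.00432, so the heart call ended. The receptor genes Bmpr2 (0.55 ± 0.09 in tail bud, 0.30 ± 0.08 in heart, 0.34 ± 0.07 in the rest) and Tgfbr2 (0.38 ± 0.09 in heart, 0.45 ± 0.07 in the rest) were among them. So were the inhibitory SMAD genes Smad6 (0.39 ± 0.08 in tail bud, 0.46 ± 0.09 in heart) and Smad7 (0.26 ± 0.07 in tail bud) and the matrix gene Thbs1 (0.56 ± 0.09 in the rest). Bmpr2, Tgfbr2 and Ccn2 are also in the target list. Hox genes rose as a group in tail bud, with 5 of 37 higher (6 adjusted over the list alone, median 0.19, adjusted p = 0.00341), a call lost with an estimated correlation (adjusted p = 0.704). Hoxa5 (0.41 ± 0.08, 0.00109), Hoxb5 (0.39 ± 0.09, 0.00576), Hoxa6 (0.34 ± 0.09, 0.0264) and Hoxb4 (0.32 ± 0.10, 0.0453), which pattern the trunk, were among the 5. In heart and in the rest of the embryo 0 of 31 and 0 of 33 Hox genes passed, also when adjusted over the list alone (1 and 2 unadjusted, 0 with DESeq2), with list adjusted p = 0.237 in both. Tail bud and segmentation genes rose in tail bud (adjusted p = 0.0418; adjusted p = 0.875 with an estimated correlation). The members past the threshold were Dll1 (0.31 ± 0.08), Tbx6 (0.26 ± 0.07) and Dll3 (0.36 ± 0.11), genes of the Notch pathway and presomitic mesoderm, as 3 of 20 (3 adjusted over the list alone; median 0.21). That call ended without wild-type replicate 1 (adjusted p = 0.0617), wild-type replicate 2 (0.206) or replicate 1 of the mutants (0.481) or over genes with a mean log2 CPM of at least 3 (0.110). In heart 0 of 18 passed, also unadjusted or with DESeq2 (list adjusted p = 0.555), and in the rest of the embryo 1 of 19 (2 adjusted over the list alone; 0.0803), the neuromesodermal gene Nkx1-2 (0.52 ± 0.15).

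Cell cycle and E2F target genes moved both ways. In tail bud 2 of 20 rose and 4 fell (2 and 6 adjusted over the list alone; list adjusted p = 0.273). In heart 1 rose and 2 fell (1 and 8; median −0.08, adjusted p = 0.00407, and 0.571 as the adjusted p with an estimated correlation). In the rest of the embryo 4 rose and 2 fell (5 and 2; adjusted p = 0.989, with a median of −0.02 and a mean of 0.01). The cyclin gene Ccne1 fell by 0.42 ± 0.07, 0.44 ± 0.08 and 0.33 ± 0.04 in the 3 tissues and the replication helicase gene Mcm5 by 0.29 ± 0.06, 0.23 ± 0.05 and 0.13 ± 0.04. Mcm3 rose by 0.18 ± 0.05 in tail bud and 0.29 ± 0.04 in the rest. Neural crest genes rose in the rest of the embryo (median 0.16, adjusted p = 0.00833; adjusted p = 0.367 with an estimated correlation), with Tfap2b (0.21 ± 0.06) as 1 of 11 past the threshold (3 adjusted over the list alone). This call ended without wild-type replicate 1 (0.0603) or at that minimum of 3 (0.0607). Primitive erythroid genes were lower in tail bud as a list (median −0.98, adjusted p = 0.00405; adjusted p = 0.892 with an estimated correlation) with 0 of 12 past the threshold, also adjusted over the list alone (1 at an unadjusted p under 0.05, 0 with DESeq2). Gata1 stood at −1.24 ± 0.58 (0.184), and the call ended without wild-type replicate 2 (0.0578) or replicate 1 of the mutants (0.0766) or at the minimum of 3 (0.0626). Visceral endoderm and yolk sac genes were lower in the rest of the embryo (median −1.42, adjusted p = 0.00516; adjusted p = 0.892 with an estimated correlation), again with 0 of 11 past the threshold, 0 adjusted over the list alone, 0 unadjusted and 0 with DESeq2. Apob stood at −2.48 (0.322), and the call ended without wild-type replicate 1 (0.253) or at the minimum of 3 (0.151).

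The remaining lists did not shift in the full knockout, with list adjusted p values of 0.719, 0.719 and 0.530 in tail bud, heart and rest of the embryo for cardiomyocyte genes, 0.877, 0.653 and 0.719 for the second heart field and 0.326, 0.671 and 0.144 for endothelium. They were 0.273, 0.755 and 0.504 for neural genes, 0.253, 0.877 and 0.947 for somite derivatives and 0.719, 0.273 and 0.504 for p53 targets. They were 0.504, 0.664 and 0.273 for hypoxia and glycolysis and 0.719, 0.459 and 0.671 for immediate early genes. Neural crest genes gave 0.877 in tail bud and 0.458 in heart, erythroid genes 0.662 in heart and 0.273 in the rest, and visceral endoderm genes 0.458 in tail bud and 0.671 in heart. Single members passed in some of them: in tail bud the cardiac factor genes Tbx20 (0.69 ± 0.21, 0.0452) and Mef2c (−0.40 ± 0.12, 0.0389), the tight junction gene Cldn5 (−0.44 ± 0.12, 0.0173) and Fgf10. They were joined there by the neuronal tubulin gene Tubb3 (0.51 ± 0.14, 0.0185) and the somite gene Pax3 (0.74 ± 0.14, 0.00144). In heart these were Tbx20 (0.30 ± 0.05, 0.00129), Tbx5 (0.22 ± 0.06, 0.0272), the muscle LIM gene Csrp3 (−0.27 ± 0.06, 0.0109) and the endothelial adhesion gene Pecam1 (0.23 ± 0.07, 0.0400). In the remaining embryo Pecam1 rose by 0.29 ± 0.06 (0.00329) and the somite gene Meox2 fell by 0.33 ± 0.10 (0.0362). Adjusted over the list alone the counts were the same for these lists, except endothelium, with 2 in tail bud and 3 in the rest of the embryo, and somite derivatives, with 2 in the rest. In the other lists above 0 members passed. Of them 0 to 4 per list and tissue had an unadjusted p under 0.05, and DESeq2 called 1 neural crest gene and 1 p53 target, both in tail bud. The list medians and test directions differed in sign for visceral endoderm genes in heart (median −0.04, mean 0.08, tested up), and the median and mean for neural genes there (0.01 and −0.10, tested down).

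In tail bud, Δ17 changed 301 genes (257 higher, 44 lower). Among those that rose were the iron exporter gene Slc40a1 (0.99 ± 0.12, adjusted p = 1.89e-05), the helicase family gene Znfx1 (0.96 ± 0.06, 2.02e-10) and, in the target list, Mylip (0.67 ± 0.11, 0.00145) and E2f1 (0.44 ± 0.06, 0.000129). Δ18 changed 22, each of them higher, led by Efcab7 (1.32 ± 0.20, 0.00228) and the DNA damage kinase gene Atm (0.67 ± 0.06, 1.56e-06). Δ19 changed 175 (100 higher, 75 lower): Lonrf1 (0.96 ± 0.13, 0.000134), Reep3 (0.93 ± 0.06, 1.60e-09) and Mylip (0.84 ± 0.11, 0.000225) rose. The TNF receptor family gene Cd40 (−0.72 ± 0.14, 0.00565), the galectin gene Lgals1 (−0.74 ± 0.14, 0.0107) and the antiproliferative gene Btg2 (−0.57 ± 0.09, 0.00204) fell. Δ92 changed 61 (55 higher, 6 lower), among them Fndc3b (0.83 ± 0.08, 3.08e-06), Atp7a (0.71 ± 0.06, 3.72e-07) and Itga5 (0.42 ± 0.04, 3.08e-06), with lower cyclin G1 (Ccng1, −0.53 ± 0.10, 0.0115) and the thiamine transporter gene Slc19a2 (−0.37 ± 0.08, 0.0265). Δ17,18 changed 1414 (729 higher, 685 lower), with Slc40a1 (1.07 ± 0.12, 8.57e-06) and the receptor gene Tgfbr2 (0.54 ± 0.11, 0.0029) higher and the esterase gene Esd (−0.74 ± 0.09, 2.68e-05) and Prrt4 (−0.74 ± 0.19, 0.0206) lower. Δ17,18,92 changed 947 (648 higher, 299 lower): Fndc3b (1.00 ± 0.08, 5.25e-08), Mylip (0.98 ± 0.11, 1.09e-05), Bmpr2 (0.50 ± 0.09, 0.00129), Bmp2 (0.52 ± 0.12, 0.00825) and Itga5 (0.44 ± 0.04, 6.94e-07) rose. The inflammasome gene Nlrp6 (−0.82 ± 0.18, 0.00636) and Fbxo6 (−0.81 ± 0.17, 0.00577) fell. Prrt4 (−0.76 ± 0.19, 0.0341) and the homeobox gene Dlx2 (−0.68 ± 0.17, 0.0298) were lower in Δ17, but without its replicate 1 their adjusted p values were 0.192 and 0.191. The calls of Prrt4 in Δ17,18 (0.108, without its replicate 2), Lgals1 (0.0735, without Δ19 replicate 1), Ccng1 (0.111, without wild-type replicate 3, and 0.0503, at −0.47, with a sex covariate) and Slc19a2 (0.176, without Δ92 replicate 2) also ended.

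Without wild-type replicates 1, 2 and 3 these tail bud counts were 554, 909 and 180 for Δ17, 573, 1194 and 78 for Δ19, and 147, 104 and 36 for Δ92. Without wild-type replicates 2 and 3 they were 2705 and 438 for Δ17,18 and 2032 and 500 for Δ17,18,92. Without wild-type replicate 2 Δ18 gave 627. Without the mutant's own replicates 1, 2 and 3 they were 159, 194 and 182 for Δ17 and 86, 83 and 68 for Δ19. Δ18 gave 14 without its replicate 2, Δ92 29 and 27 without its replicates 1 and 3, Δ17,18 365 and 451 without its replicates 2 and 3, and Δ17,18,92 472 and 475 without its replicates 1 and 2. When only the 6 libraries of a comparison were fitted, they came to 3, 0, 10, 0, 7 and 79 for Δ17, Δ18, Δ19, Δ92, Δ17,18 and Δ17,18,92, with 730 and 737 genes at an unadjusted p under 0.05 for Δ18 and Δ92. In these fits 2 of 10, 0 of 2, 3 of 13, 0 of 7, 1 of 22 and 6 of 23 named genes kept their calls. DESeq2 on all tail bud libraries gave 458 for Δ17, 61 for Δ18, 501 for Δ19 and 161 for Δ92.

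In heart, Δ17 changed 93 genes (85 higher, 8 lower), with Clip4 (0.80 ± 0.09, adjusted p = 2.98e-05), Zbtb4 (0.44 ± 0.08, 0.00303) and E2f1 (0.38 ± 0.06, 0.000418) higher and Uggt2, a glycoprotein folding sensor (−0.68 ± 0.09, 8.67e-05), and Gpr180 (−0.41 ± 0.09, 0.0178) lower. Δ18 changed 7, each higher, with Dtx3l, a ubiquitin ligase (1.04 ± 0.18, 0.0156), and Atm (0.44 ± 0.06, 0.00102). Δ19 changed 68 (35 higher, 33 lower), among them Epb41l4a (1.12 ± 0.14, 8.80e-05) and Tcp11l2 (0.69 ± 0.12, 0.00315), which rose, and the calcium channel subunit gene Cacna2d1 (−0.71 ± 0.10, 0.000474) and AW551984 (−0.73 ± 0.13, 0.00383), which fell. Δ92 changed 12 (10 higher, 2 lower), with the galactosidase gene Gla (0.54 ± 0.09, 0.0113) and Atp7a (0.53 ± 0.08, 0.00115) higher and Igfbpl1 (−0.36 ± 0.07, 0.0237) and the guanylate cyclase gene Gucy1a1 (−0.35 ± 0.07, 0.0413) lower. Δ17,18 changed 187 (159 higher, 28 lower), with Chrm2 (1.26 ± 0.24, 0.0104) and the microfibril gene Mfap4 (1.11 ± 0.26, 0.0375) higher and Scn4b (−0.70 ± 0.16, 0.0375) and Uggt2 (−0.65 ± 0.09, 0.000136) lower. Δ17,18,92 changed 316 (261 higher, 55 lower), with Slc35d3 (1.05 ± 0.20, 0.00355), Tgfbr2 (0.49 ± 0.09, 0.00328) and Pecam1 (0.34 ± 0.06, 0.00364) higher and the splicing factor gene Rbfox3 (−1.01 ± 0.16, 0.000591) and Wfikkn1 (−0.97 ± 0.19, 0.00466) lower.

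Single libraries also moved the heart counts. Without wild-type replicates 1, 2 and 3 they were 44, 43 and 43 for Δ17 and 64, 103 and 112 for Δ17,18. Without replicates 1 and 2 they were 29 and 24 for Δ19 and 127 and 207 for Δ17,18,92, without replicates 1 and 3 they were 2 and 4 for Δ92. Δ18 gave 4 without replicate 2. Without the mutant's own replicates 1, 2 and 3, Δ19 gave 38, 31 and 168 and Δ17,18 339, 98 and 95. Δ17 gave 32 and 44 without its replicates 1 and 2, Δ18 3 and 3 without its replicates 1 and 3, Δ92 3 and 3 without its replicates 2 and 3, and Δ17,18,92 172 without its replicate 1. Fitting only the 6 libraries gave 130 for Δ19. Without wild-type replicate 1 the calls of Gpr180 in Δ17 (adjusted p = 0.180), Chrm2 in Δ17,18 (0.0736), Wfikkn1 (0.0600) and AW551984 (0.0522) ended, and without wild-type replicate 3 those of Mfap4 (0.174), Dtx3l (0.180) and Gucy1a1 (0.364). Those of Gla (0.139) and Igfbpl1 (0.173) ended without Δ92 replicate 3, and that of Scn4b in Δ17,18 (0.155) without its replicate 3.

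In the rest, Δ17 changed 274 genes (250 higher, 24 lower). Among them were the semaphorin gene Sema7a (0.81 ± 0.14, adjusted p = 0.000518), Tgfbr2 (0.48 ± 0.07, 8.07e-05), Mcm3 (0.35 ± 0.04, 4.12e-07) and E2f1 (0.34 ± 0.05, 1.83e-05), which rose, and Gpr180 (−0.52 ± 0.07, 2.84e-05) and Adnp (−0.52 ± 0.13, 0.0330), which fell. Δ18 changed 63 (47 higher, 16 lower), with Efcab7 (1.05 ± 0.15, 0.000485) and the complement regulator Cd59a (0.85 ± 0.17, 0.0127) higher and the p53 target Eda2r (−0.57 ± 0.12, 0.0224) and the GMP synthetase gene Gmps (−0.22 ± 0.04, 0.00384) lower. Δ19 changed 329 (173 higher, 156 lower), with Rnf11 (0.95 ± 0.06, 4.06e-12), Lonrf1 (0.87 ± 0.08, 5.26e-08) and Mylip (0.44 ± 0.08, 0.00336) higher and AW551984 (−0.75 ± 0.13, 0.000714) and Pla2g7 (−0.59 ± 0.14, 0.0218) lower. Δ92 changed 103 (94 higher, 9 lower), with Cd59a (1.14 ± 0.17, 0.000139), the muscle gene Synpo2l (0.76 ± 0.16, 0.0195) and Itga5 (0.48 ± 0.05, 5.09e-08) higher and Eda2r (−0.91 ± 0.12, 4.14e-05) and Ccng1 (−0.58 ± 0.07, 4.14e-05) lower. Δ17,18 changed 778 (492 higher, 286 lower), with Hbb-bs (1.07 ± 0.25, 0.0159), the nuclear receptor gene Nr4a3 (0.92 ± 0.16, 0.000474), Ccn2 (0.54 ± 0.09, 0.000178) and Smad6 (0.42 ± 0.07, 0.000512) higher. The Rab regulator gene Tbc1d4 (−0.82 ± 0.20, 0.0273) and Esd (−0.56 ± 0.08, 5.14e-05) were lower. Δ17,18,92, with 2 libraries, changed 984 (747 higher, 237 lower), among them the calponin gene Cnn1 (1.11 ± 0.21, 0.00171), Zbtb4 (0.81 ± 0.13, 0.000184), Cdkn1a (0.60 ± 0.11, 0.000962), Tgfbr2 (0.54 ± 0.08, 3.05e-05) and Itga5 (0.52 ± 0.05, 3.19e-08), which rose. The cytokine receptor gene Csf2rb (−1.24 ± 0.32, 0.0346) and Tmem56 (−1.03 ± 0.18, 0.000934) fell. Cardiomyocyte genes rose as a list in this tissue of Δ17,18,92 (median 0.76, 10 of 24 higher, adjusted p = 2e-11; adjusted p = 0.291 with an estimated correlation).

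The counts of the rest were 181 for Δ17 and 67 for Δ92 without wild-type replicate 3, and 29 and 41 for Δ18 without wild-type replicates 1 and 3. They were 142, 203 and 216 for Δ19 without wild-type replicates 1, 2 and 3, 333 and 474 for Δ17,18 without wild-type replicates 1 and 3, and 611 for Δ17,18,92 without wild-type replicate 1. Without the mutant's own libraries they were 35 and 35 for Δ18 (replicates 1 and 3) and 156 for Δ19 (replicate 1). They were 375 and 468 for Δ17,18 (replicates 2 and 3) and 634 and 376 for Δ17,18,92 (replicates 1 and 2, with the remaining library taken to vary like the other groups). Fitting only the libraries compared gave 178 for Δ19 and 1267 for Δ17,18. The calls of Adnp (adjusted p = 0.1997, without Δ17 replicate 2), Cd59a and Eda2r in Δ18 (0.1996 and 0.1397, without its replicate 1), Gmps (0.103, without wild-type replicate 1), Pla2g7 (0.187, without Δ19 replicate 1), Synpo2l (0.132, without wild-type replicate 3), Hbb-bs and Tbc1d4 (0.130 and 0.143, without Δ17,18 replicate 2), Cnn1 (0.0919, without Δ17,18,92 replicate 2) and Csf2rb (0.273, without its replicate 1) ended, as did Esd in Δ17,18 with only the libraries compared (0.0541).

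To ask which genes respond to loss of each seed family's cluster members, the 8 genotypes were fitted with 1 additive term per family. Loss of miR-17 with miR-20a raised Znfx1 in tail bud (0.84 ± 0.04, adjusted p = 4.32e-15) and heart (0.67 ± 0.04, 2.87e-13). It raised the mitochondrial fusion gene Mfn2 in tail bud and the rest of the embryo (0.42 ± 0.03 and 0.42 ± 0.02) and the RNA polymerase III subunit gene Polr3g in tail bud and heart (0.51 ± 0.03 and 0.43 ± 0.03). Also higher were Ankrd13c in tail bud (0.43 ± 0.03) and, in heart, Clip4 (0.84 ± 0.05, 7.64e-12) and the circadian factor gene Clock (0.42 ± 0.03). The rest added the cytokinesis kinesin Kif23 (0.41 ± 0.02), Plekha3 (0.60 ± 0.04) and Jpt1 (0.35 ± 0.02). The steroid dehydrogenase gene Hsd11b2 (−0.34 ± 0.04) and the p38 kinase gene Mapk11 (−0.33 ± 0.05) fell in tail bud. So did Scn4b (−0.74 ± 0.09) and the phosphatase gene Dusp9 (−0.39 ± 0.05) in heart, and Spred3 (−0.33 ± 0.04) and Pdxk, which makes active vitamin B6 (−0.23 ± 0.03), in the rest. Loss of miR-18 raised Trappc10 in tail bud and the rest (0.30 ± 0.04 and 0.30 ± 0.03, adjusted p = 0.000148 and 1.67e-06). It raised the xylosyltransferase gene Xylt2 in tail bud and the rest (0.25 ± 0.04 and 0.28 ± 0.04). Also higher were Tcaf2 (0.45 ± 0.07) in tail bud and, in heart, the exoribonuclease gene Eri1 (0.21 ± 0.03), Zfp367 (0.28 ± 0.05) and Snx13 (0.19 ± 0.03). The rest added Smad2, a TGF-β effector (0.21 ± 0.03), and Zfp651 (0.26 ± 0.04). Atp9a (−0.26 ± 0.05) and Lrrc4 (−0.33 ± 0.07) fell in tail bud, Ccne1 (−0.28 ± 0.05) in heart, and Ogfr (−0.14 ± 0.02) and Taf7 (−0.21 ± 0.04) in the rest.

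Loss of miR-19 raised the Polycomb gene Suz12 in all 3 tissues (0.62 ± 0.03, 0.44 ± 0.03 and 0.71 ± 0.02, adjusted p = 9.58e-14, 8.05e-12 and 5.91e-24 in tail bud, heart and rest). It raised Rnf11 likewise (0.89 ± 0.04, 0.39 ± 0.03 and 0.93 ± 0.03). Acadm, the medium-chain fatty acid dehydrogenase, rose by 0.85 ± 0.03 in tail bud and 0.82 ± 0.04 in the rest, Reep3 by 0.75 ± 0.04 and 0.74 ± 0.03, and Nbeal2 (0.64 ± 0.06) and Spryd3 (0.49 ± 0.04) rose in heart. The matrix genes Mfap4 (−0.43 ± 0.04) and Emilin1 (−0.33 ± 0.04) fell in tail bud, the annexin gene Anxa2 (−0.45 ± 0.05) and the GTPase gene Rhoc (−0.30 ± 0.04) in heart, and AW551984 (−0.71 ± 0.08) and Mfn2 (−0.19 ± 0.02) in the rest. Loss of miR-92 raised the Golgi mannosidase gene Man2a1 (0.60 ± 0.03, 0.38 ± 0.04 and 0.68 ± 0.03, adjusted p = 3.49e-14, 8.45e-08 and 1.41e-19) in all 3 tissues. Itga5 rose by 0.41 ± 0.02 in tail bud and 0.52 ± 0.03 in the rest, Lhfpl2 by 0.55 ± 0.03 in tail bud and Fndc3b by 0.77 ± 0.02 in the rest. In heart the WNT antagonist family gene Dkk3 (0.48 ± 0.04) and Necap1 (0.27 ± 0.03) rose. Mapk8ip2 (−0.60 ± 0.08) and Ric3 (−0.29 ± 0.04) fell in tail bud, Igfbpl1 (−0.34 ± 0.04) and Gucy1a1 (−0.29 ± 0.04) in heart, and Cpt1c (−0.31 ± 0.04) and Carmil3 (−0.41 ± 0.06) in the rest.

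In tail bud the terms for miR-17, miR-18, miR-19 and miR-92 changed 926 (698 higher), 55 (43), 906 (492) and 623 (468) genes. In heart they changed 604 (476), 15 (14), 732 (314) and 264 (208), and in the rest 1311 (838), 131 (99), 1154 (591) and 907 (643). Genes that rose held an 8mer or 7mer-m8 of the lost family far more often than all tested genes with a 3′ untranslated region. For miR-17 the shares were 66.8%, 61.4% and 61.1% of the risen genes against 14.8%, 14.9% and 14.8% of those tested in tail bud, heart and rest. They were 78.6%, 71.4% and 71.6% against 10.2% in each tissue for miR-18, 45.3%, 41.0% and 45.0% against 13.8%, 13.9% and 13.7% for miR-19, and 44.9%, 47.3% and 40.4% against 7.93%, 7.88% and 7.92% for miR-92. The odds ratios ran from 4.54 (miR-19, heart) to 33.2 (miR-18, tail bud), with Fisher's exact test adjusted p between 5.31e-220 and 8.46e-08. Genes are not independent replicates, so these p values describe the lists.

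Without tail bud wild-type replicate 3 the tail bud counts rose to 131 for miR-18, 1389 for miR-19 and 986 for miR-92. The miR-18 count there fell to 35 without Δ17 replicate 2 and to 33, 34 and 26 without Δ18 replicates 1, 2 and 3, and the miR-19 count to 570 without full knockout replicate 3 and to 559 and 597 without Δ19 replicates 1 and 2. In heart the miR-17 count fell to 379 without Δ17 replicate 1 and the miR-18 count to 6, 7 and 9 without Δ18 replicates 1, 2 and 3. The miR-19 count there fell to 472 without full knockout replicate 3 and to 278 and 468 without Δ19 replicates 1 and 2. The miR-18 count of the rest was 79 and 81 without Δ17 replicates 2 and 3, 71 without Δ18 replicate 3 and 221 without Δ19 replicate 1. Of the 71 named genes, 4 lost their call in such a fit, all in the miR-18 term. In heart these were Snx13, Zfp367 and Ccne1 without Δ18 replicate 1 (adjusted p = 0.0581, 0.0606 and 0.0506), and Ccne1 also without Δ18 replicate 2 (0.0533). In tail bud the call of Lrrc4 ended in 9 of 24 fits (0.0504 to 0.165), those without wild-type replicate 1, Δ17 replicate 3, Δ18 replicates 1 and 3, Δ19 replicate 2, Δ92 replicates 1 and 2 and Δ17,18 replicates 2 and 3. Leaving out all full knockout libraries lowered the miR-19 counts to 176, 239 and 419 in tail bud, heart and rest and the miR-92 counts to 313 in tail bud and 582 in the rest, and gave 30 and 235 for miR-18 in tail bud and the rest. DESeq2 gave 183, 47 and 250 for miR-18 and 402 for miR-92 in heart.

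**Figure D3:**
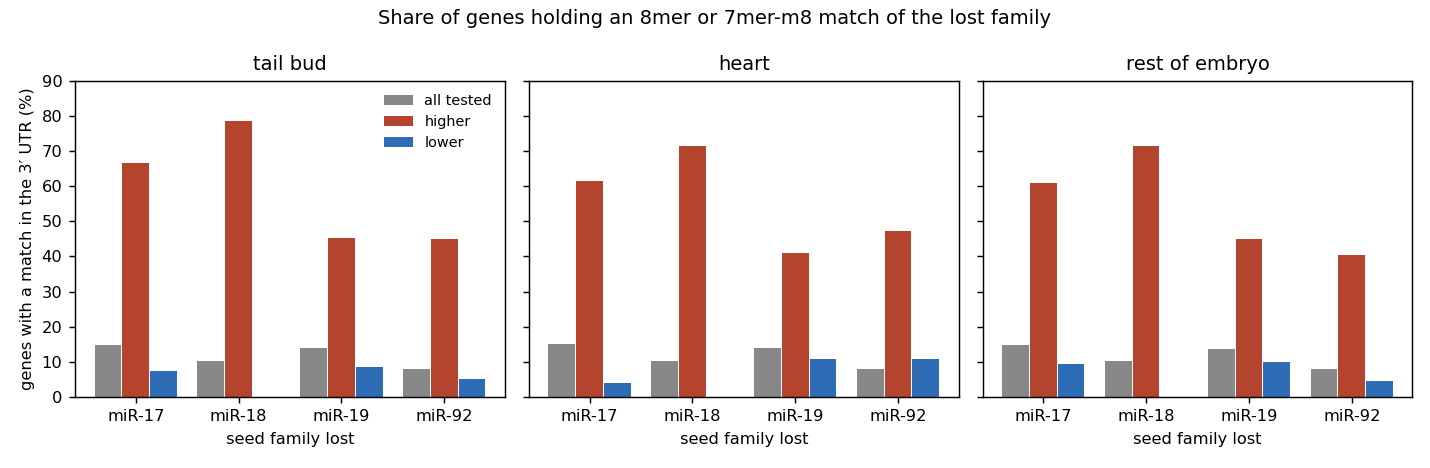
Share (%) of genes with an 8mer or 7mer-m8 match of the lost family in the 3′ untranslated region, for all tested genes and for genes that rose or fell with loss of that family, by tissue. Among genes that rose the shares run from 40.4% to 78.6%, and among all tested genes from 7.88% to 14.9%.

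Genes with an 8mer of a family were followed as a set in each library. Loss of the family shifted its own set upward in 10 of 12 cases. The miR-17 sets (617, 619 and 633 genes in tail bud, heart and rest) rose by 0.15, 0.13 and 0.13 (11.0%, 9.10% and 9.65%; permutation test over the 24, 24 and 23 libraries, adjusted p = 0.00024 in each). The miR-92 sets rose by 0.13, 0.09 and 0.12 (0.0004, 0.00282 and 0.00024) and the miR-19 sets by 0.08, 0.04 and 0.07 (0.00048, 0.0109 and 0.000384). The miR-18 set rose in the rest (0.07, adjusted p = 0.0109) and stood at 0.07 in tail bud (0.0659) and 0.04 in heart (0.269). The tail bud value passed without wild-type replicate 3 (0.06, adjusted p = 0.0360) or Δ17 replicate 1 (0.08, 0.0466), and with camera in place of the permutation test. The call in the rest ended without Δ18 replicate 1 (0.0879), with 7mer-m8 sites added (0.0637) or with medians of log2 CPM (0.0551). The heart call of miR-19 ended without the full knockout libraries (0.138), with 7mer-m8 sites added (0.375) or with medians (0.231), and that of miR-92 in heart with 7mer-m8 sites added (0.0868). Of 36 pairings of a set with the loss of another family, 2 rose, both in heart with loss of miR-17: the miR-18 set (0.06, 0.0386) and the miR-19 set (0.04, 0.0190). Both calls ended without Δ17 replicate 1, 2 or 3 or Δ18 replicate 1 (0.0515 to 0.180), and that of the miR-18 set also without full knockout replicate 1 or 3 or Δ92 replicate 3 (0.0502 to 0.0511).

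Taken genotype by genotype with camera, the set of a family rose in 39 of 39 comparisons in which the genotype lacks that family, and in 7 of 45 in which it keeps it, where 3 fell. The 7 were the miR-18 set in Δ17 in tail bud, heart and rest (medians 0.09, 0.07 and 0.04), the miR-17 and miR-92 sets in tail bud Δ18 (0.05 and 0.05), and the miR-19 set in tail bud Δ17 and Δ17,18,92 (0.03 and 0.05). With an estimated correlation 3 of the 7 remained, those of the miR-18 set in Δ17 (adjusted p = 0.00595, 0.00281 and 0.0296). Without wild-type replicate 3 in every tissue the count of kept families was 3.

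**Figure D4:**
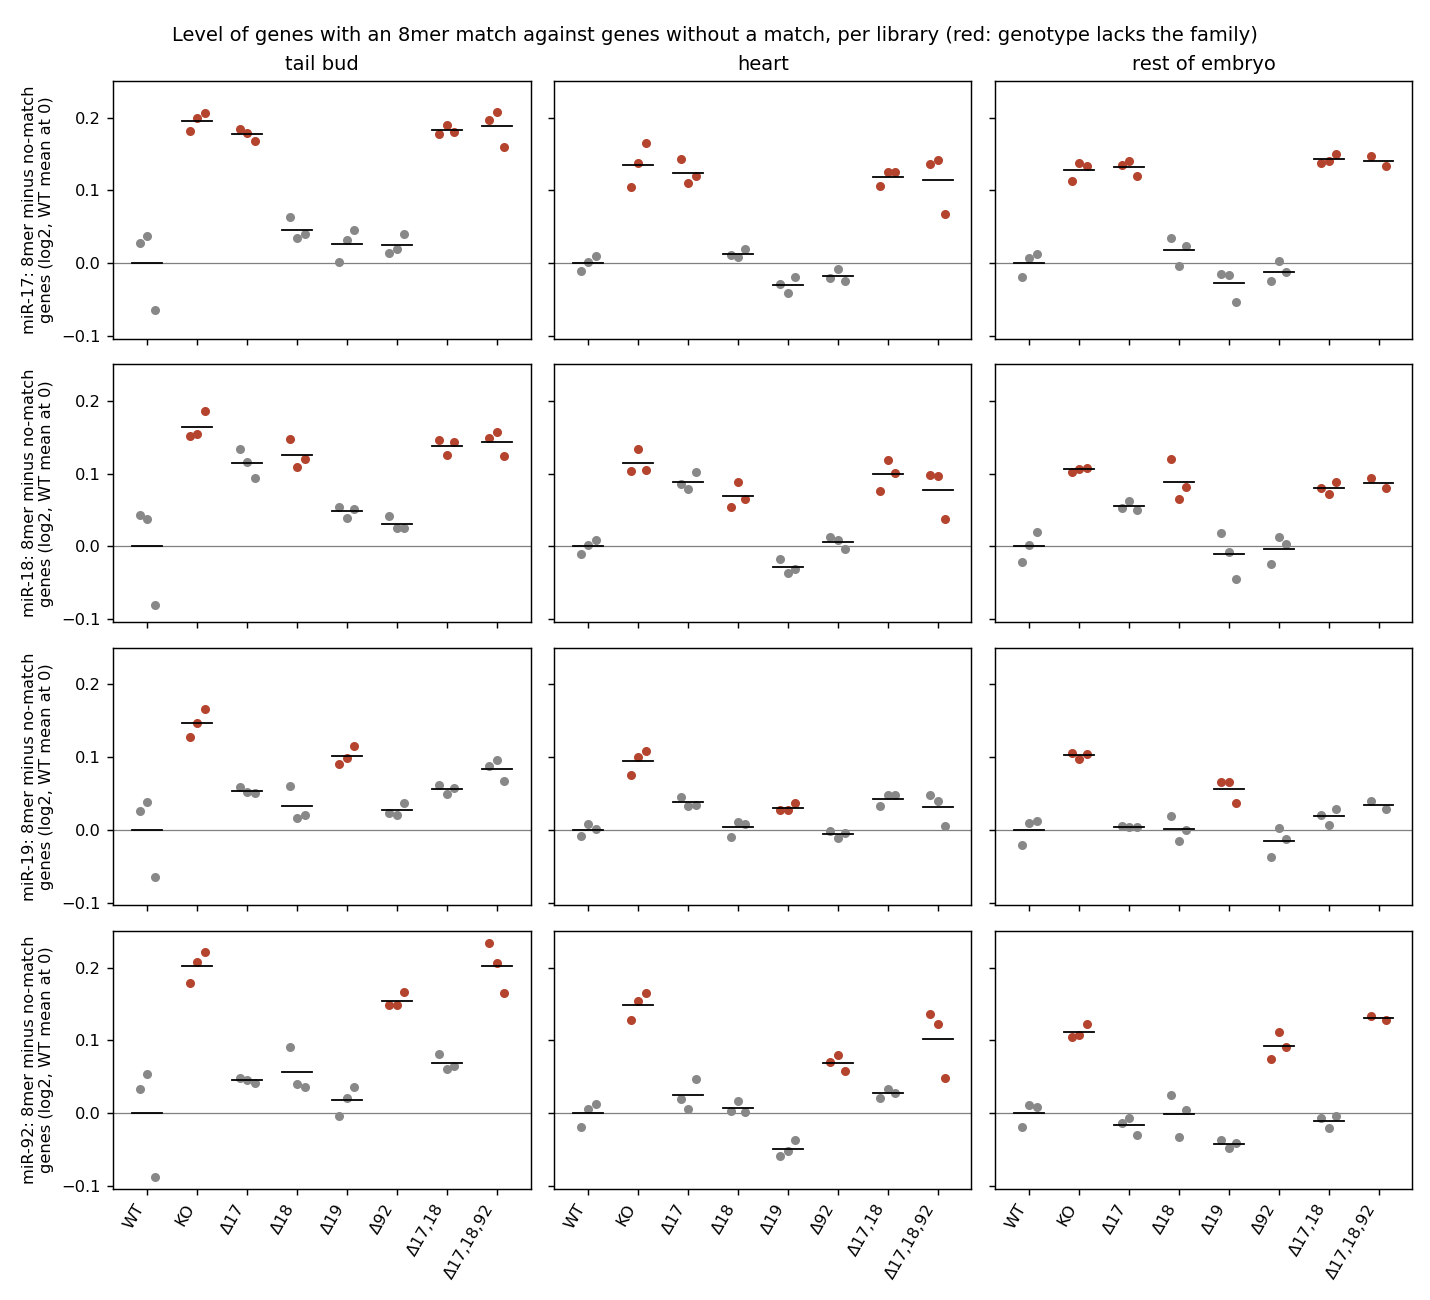
Mean log2 CPM of genes with an 8mer of a family minus that of genes without a match, per library, by genotype (columns) and family (lines of panels), with the wild-type mean set to 0; points are libraries and bars are group means. Libraries of genotypes that lack the family are red, and the shift per family loss runs from 0.04 to 0.15.

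Few genes passed the test of departure from additivity of the 4 families. In tail bud these were 3 of 17009 genes (876 at an unadjusted p under 0.05): Mir17hg (adjusted p = 0.0051), Gpr180 (0.0172), which was lower in Δ17, Δ19 and Δ17,18 (−0.63, −0.62 and −0.60) with 0.04 in the full knockout, and Efcab7 (0.0474; 1.32 in Δ18 and −0.03 in the full knockout). In heart these were 10 genes (1898 of 16750 at an unadjusted p under 0.05), led by Uggt2 (0.001; −0.68 in Δ17 and 0.19 in the full knockout). Phyhip (0.00965; 2.77 in Δ17,18 and 0.01 in the full knockout) was also among them. The rest of the embryo held 18 (1583 of 17512 unadjusted), led by Atm (1.97e-05; 0.65 in the full knockout, 0.55 in Δ18 and −0.09 in Δ19), the midbrain homeobox gene En2 (2.99e-05; 0.55 in Δ17,18 and −0.47 in Δ17,18,92) and Mir17hg (3.18e-05). There Eda2r (0.00992) and Cd59a (0.0133) passed too, with Cd59a at 0.05 in the full knockout and −0.06 in Δ17,18,92. Of the genes that passed, Mir17hg, Gpr180, Uggt2, Phyhip, Ptk2b, Esd and Sox21 lie on chromosome 14 with the locus, where variants linked to an allele would also give departure. The test for Efcab7 in tail bud ended in 19 of 24 fits that left out 1 library (adjusted p up to 0.333, without wild-type replicate 3) and passed in 5. It ended also without a filter on low counts (0.106), with the replicate block (0.0580) and with a sex covariate (0.0875). The test for Gpr180 ended without full knockout replicate 2 (0.0501) or Δ17,18 replicate 2 (0.0509), with a sex covariate (0.0875) and without the full knockout libraries (0.207). Without the full knockout libraries the tests for Mir17hg (0.845 in tail bud, 0.372 in the rest) and Uggt2 (0.282) ended as well.

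The counts of departing genes depended on single libraries and on the tool. In tail bud the count was 1 without full knockout replicate 2, without Δ17,18 replicate 2, with a sex covariate or without the full knockout libraries, and 11 with DESeq2. In heart it was 47 without Δ17,18 replicate 2, 33 without Δ17,18 replicate 1 and 29 without Δ17,18,92 replicate 1. It was 4 to 6 without any 1 of 10 other libraries. With DESeq2 it was 197 in heart and 73 in the rest, without a filter on low counts 1011 and 521, and without the full knockout libraries 1 and 6. A sex covariate gave 3 in heart, and the count in the rest was 10 without wild-type replicate 1. The heart library Δ17,18 replicate 2 stood apart from its group by −0.90 in erythroid, 0.50 in visceral endoderm, 0.40 in neural, 0.32 in second heart field and in somite and −0.30 in endothelial genes.

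Whether the full knockout acts differently in the 3 tissues was tested with an interaction term over 18 libraries, which 7 of 17548 genes passed (1259 at an unadjusted p under 0.05). Acadm rose less in heart (0.18) than in tail bud (0.79) and the rest of the embryo (0.74; adjusted p = 0.000794). Zfp568 (0.39, −0.01 and 0.41 in tail bud, heart and rest, 0.0207) and Triobp, an actin-binding gene (0.64, 0.15 and 0.47, 0.0323), were also lowest in heart. Clip4 (0.25, 0.96 and 0.06; 0.0167) and 1700020I14Rik (0.26, 0.53 and 0.04; 0.0293) were highest in heart. The calcium-binding gene Efhd2 stood at −0.53, 0.05 and −0.25 (0.0268) and the chloride transporter gene Clcn5 at 0.15, −0.23 and 0.06 (0.0323). The count was 24 and 39 without tail bud wild-type replicates 2 and 3, 2 and 2 without tail bud knockout replicates 2 and 3, 3, 1 and 2 without heart wild-type replicates 1, 2 and 3, and 3 and 1 without heart knockout replicates 2 and 3. It was 2 and 4 without wild-type and 4 and 2 without knockout replicates 2 and 3 of the rest, 97 with DESeq2 and 44 without a filter on low counts. The calls of Clip4, Zfp568, Efhd2, Clcn5 and Triobp ended in 3, 8, 10, 13 and 14 of 18 fits that left out 1 library (adjusted p up to 0.113 for Clip4, Zfp568 and Efhd2, without heart knockout replicate 3, and 0.176 and 0.168 for Clcn5 and Triobp, without heart wild-type replicate 2). That of Acadm ended in 0 of 18, and 1700020I14Rik, outside the naming rule and named after its values were seen, was not followed in these fits. For other genes, a change past the threshold in 1 tissue and not in another is not shown to differ between tissues.

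Among wild-type libraries the tissues differed in their marker genes. Heart held the contractile and secretory genes of cardiac muscle: Myl2, a ventricular myosin light chain, at 2087 ± 160 CPM against 0.199 ± 0.149 in the rest of the embryo (log2 13.63 ± 0.37, adjusted p = 1.88e-10). Myl3 stood at 1324 ± 60.0 against 3.37 (8.88 ± 0.15), and the natriuretic peptide genes Nppa (9.28 ± 0.27) and Nppb (9.11 ± 0.58) were also higher. Against tail bud, where Xirp1, Nppa, Fsd2 and Klhl30 had 1 or 2 counts in total, the ratios of CPM were 12230 (95% interval 3385 to 101000) for Xirp1, 12240 (2197 to 483600) for Nppa, 11670 (2094 to 461000) for Fsd2 and 8122 (1457 to 320900) for Klhl30. Tail bud held the posterior genes Hoxc10 at 264.9 ± 11.0 CPM against 1.83 ± 1.27 in heart, Cdx2 at 203.0 ± 24.8 against 1.26, Nkx1-2 at 105.2 against 0.673 and Hoxb5os, an antisense transcript whose reads may include Hoxb5 reads, at 96.4 against 0.566. Against the rest of the embryo, Hoxc10 (6.83 ± 0.24, 1.25e-08), Cdx4 (6.53 ± 0.44), Hoxa10 (6.39 ± 0.32) and the mesoderm gene T (5.64 ± 0.21) were higher in tail bud. There the receptor gene Erbb4 was lower (−5.40 ± 0.29), and Xirp1, Klhl30 and Fsd2 were 105.9-fold (29.0 to 880.4), 93.8-fold (16.4 to 3745) and 89.8-fold (15.7 to 3586) lower, from 1 or 2 counts. The rest exceeded heart in the neural gene Sox2 (109.1 ± 7.43 against 1.48 CPM), the somite gene Meox1 (117.6 against 1.74), the epithelial gene Cldn6 (62.7 against 0.957) and Hoxb9 (88.9 against 1.61). In all, 11611 of 16922 genes differed between heart and tail bud (5725 higher in heart), 11524 between heart and the rest (5752 higher) and 5051 between tail bud and the rest (2233 higher in tail bud).

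Y-linked genes were expressed by 2 of 3 replicate numbers in wild type, 3 in the full knockout, 2 in Δ17, 1 in Δ18, 1 in Δ19, 0 in Δ92, 1 in Δ17,18 and 2 in Δ17,18,92. In the full knockout 0 sex-linked genes passed (1, 0 and 1 at an unadjusted p under 0.05 in tail bud, heart and rest, and 0, 1 and 0 with DESeq2), with Xist at −7.71, −6.17 and −7.43 (adjusted p = 0.172, 0.329 and 0.241). Adding the level of Y-linked genes as a covariate lowered the counts for Δ92 to 7 in heart and 65 in the rest.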

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

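The tests of scaling, of E2F-driven transcription, of hairpin number, of Gpr180 in the alleles without miR-17 and of cardiomyocyte genes across tissues were chosen only after the result was seen.

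The effect of the full knockout differed between the tissues, by the interaction test, for Acadm (adjusted p = 0.000794), Clip4 (0.0167), Zfp568 (0.0207), Efhd2 (0.0268), 1700020I14Rik (0.0293), Clcn5 (0.0323) and Triobp (0.0323). Whether chance gives a count of 7 stays open. Of 61 splits of the 18 libraries, 6, the real one included, gave as many, with 988 as the highest of the others. These 5 others each reversed the knockout labels of at least 1 whole tissue, which turns the knockout effect itself into a difference between tissues, as did 4 of the 55 with fewer genes, and the splits ignored the numbers that samples share across tissues. The splits without a reversed tissue gave at most 3 genes.

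The first pattern is the higher host RNA Mir17hg in mutants of its own locus. Scaling of the libraries is argued against, because over 39 combinations of setting and tissue the log2 fold change in the full knockout stayed between 1.39 and 1.88 (highest adjusted p = 0.000841). Mcm7, which hosts the related cluster, reached at most 0.11, against higher transcription of E2F-driven loci, but it is 1 gene, and E2f1 itself rose (0.37, 0.35 and 0.33 in tail bud, heart and rest), so it stays open. Over the 8 genotypes the log2 fold change of Mir17hg rose with the number of hairpins deleted, with Spearman's rho of 0.964, 0.916 and 0.928 in tail bud, heart and rest (exact permutation p, adjusted over the 3 tissues, 0.00179, 0.00318 and 0.00268) and Pearson's r of 0.899, 0.933 and 0.911 (0.00119 in each), and 0.946, 0.931 and 0.931 without the full knockout and wild type, though Δ17,18,92, with 4 deleted, lay above the full knockout, with 6, in tail bud (1.71 against 1.48) and rest (1.585 against 1.483), and Δ18 and Δ92, with 1 each, differed (0.09 and 0.39 in tail bud). A candidate explanation is that host RNA is spared where fewer hairpins are cut out of it, and loss of repression by the microRNAs themselves was not tested and stays open.

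The second pattern is that genes near the locus on chromosome 14 changed in some alleles, such as Gpr180, lower in Δ17, Δ19 and Δ17,18, and Tgds, named after its values were seen, lower in Δ19 (−0.51, −0.47 and −0.44 in tail bud, heart and rest). Loss of miR-17 and miR-20a as the cause for Gpr180 is argued against, since the full knockout and Δ17,18,92 lack the same hairpins and their lowest value over the tissues was 0.0389. In the heart of Δ19, 4 of the 100 tested genes nearest the locus changed, against 0.378% of the others, a ratio of shares of 10.57 (Fisher's exact test, adjusted p = 0.0144; 3.98 and 3.797 in its tail bud and rest, 0.0705 and 0.0288, and 4.60 in Δ17,18 heart, 0.0360; 3 of 21 ratios passed), so a stretch of another strain's chromosome 14 linked to the allele may contribute. A direct effect of the deletion on its neighbours cannot be told apart from this, because the full knockout, with a highest ratio of 1.542, lay between the values the test set for and against it.

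The third pattern is the higher cardiomyocyte genes in the rest of the embryo of Δ17,18,92 (median 0.76 over 24 genes, camera adjusted p = 2e-11; adjusted p = 0.291 with an estimated correlation). A change of these genes in every tissue of the genotype is argued against by its heart, where the list's median was 0.00782. Heart tissue left in the dissected remainder may account for it. A set of 100 other genes with the largest wild-type excess in heart over the rest had a median of 0.60, 97% of them above 0 and 35 past the threshold (medians of 0.25, 0.20 and 0.18, with 86%, 88% and 83% above 0, in Δ92, Δ17,18 and Δ17), and the median share of heart RNA that would give their rise was 0.699% (quartiles 0.462% and 1.04%). Without replicate 2 of this group of 2, the adjusted p values of Tnni3, Ryr2, Tnnt2 and Myl4 were 0.127, 0.182, 0.240 and 0.352.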

How the results depend on the processing

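Leaving out each library in the additive model and its seed-match scores was chosen only after the data were seen; all other alternatives were fixed before. With DESeq2's size factors all 43 comparisons kept their side of the threshold or stayed within 1.5 times their count. So did 55 of 55 with the replicate number as a block (1806, 589 and 1134 genes in the full knockout of tail bud, heart and rest, and 10 for the tissue interaction). Across genotypes a number joins different embryos, so the block tests pairing only in wild-type tissues. The numbers pair the wild-type tissues less clearly for tail bud with heart, where same-numbered deviations correlated at 0.0916 or more (2 of 3 over 0.1), and each wild-type sample correlated best with its own number (3 of 3 in each pair of tissues). Leaving out 1 library gave 758 to 2839 genes for the full knockout, 159 to 909 for Δ17, 14 to 627 for Δ18, 68 to 1194 for Δ19, 27 to 147 for Δ92, 365 to 2705 for Δ17,18 and 472 to 2032 for Δ17,18,92 in tail bud. In heart the ranges were 260 to 467, 32 to 67, 3 to 7, 24 to 168, 2 to 10, 64 to 339 and 127 to 283. In the rest they were 781 to 894, 181 to 203, 29 to 74, 142 to 408, 67 to 76, 333 to 582 and 376 to 848. For miR-17, miR-18, miR-19 and miR-92 they were 648 to 1250, 26 to 131, 559 to 1389 and 460 to 986 in tail bud. They were 379 to 733, 6 to 21, 278 to 837 and 179 to 268 in heart, and 921 to 1419, 71 to 221, 822 to 1174 and 730 to 975 in the rest. Departure from additivity gave 1 to 4, 4 to 47 and 10 to 25 genes, the interaction 1 to 39, the lists 10 to 16, sets of a kept family 3 to 10 and of a lost family 38 to 39. The wild-type tissues gave 10873 to 12305 (heart and tail bud), 10801 to 10990 (heart and rest) and 3844 to 5866 (tail bud and rest). Set shifts ranged in tail bud, heart and rest from 0.1451 to 0.1544, 0.1192 to 0.1283 and 0.129 to 0.1372 for miR-17. They ranged from 0.0578 to 0.0773, 0.0347 to 0.0513 and 0.0542 to 0.0715 for miR-18 and 0.0739 to 0.0867, 0.0384 to 0.0467 and 0.0686 to 0.0766 for miR-19. For miR-92 they were 0.1296 to 0.1379, 0.0864 to 0.0995 and 0.1183 to 0.1285. A sex covariate gave 1 and 3 genes for additivity in tail bud and heart and 7 and 65 for Δ92 in heart and rest. Fitting only the groups compared gave 198, 3, 0, 10, 0, 7 and 79 genes in tail bud (edgeR; the zeros with 730 and 737 at an unadjusted p under 0.05). It gave 1010 for the full knockout and 130 for Δ19 in heart, and 178 for Δ19 and 1267 for Δ17,18 in the rest. Without the full knockout libraries the counts were 1, 1 and 6 for additivity, 30 and 235 for miR-18 in tail bud and rest, 176, 239 and 419 for miR-19, and 313 and 582 for miR-92 in tail bud and rest. The heart miR-19 shift was 0.0299 (adjusted p = 0.138). DESeq2 gave 458, 61, 501 and 161 for Δ17, Δ18, Δ19 and Δ92 in tail bud, 173, 224, 27 and 332 for Δ17, Δ19, Δ92 and Δ17,18 in heart, and 173 for Δ18 in the rest. It gave 183, 47 and 250 for miR-18, 402 for miR-92 in heart, 11, 197 and 73 for additivity and 97 for the interaction. Without a filter on low counts heart gave 1003, 298, 222, 630, 105, 749 and 776 genes and 1011 for additivity. The rest gave 457, 450, 593, 328 and 1212 for Δ17, Δ18, Δ19, Δ92 and Δ17,18 and 521 for additivity, and the interaction 44. With 7mer-m8 sites added the shifts were 0.0204 (adjusted p = 0.375) and 0.0423 (0.0868) for miR-19 and miR-92 in heart and 0.0353 (0.0637) for miR-18 in the rest, and 11 sets of a kept family rose. Medians of log2 CPM gave 0.0284 (0.231) for miR-19 in heart and 0.0437 (0.0551) for miR-18 in the rest. Camera gave 0.0636 and 0.0404 for miR-18 in tail bud and heart (adjusted p = 9.82e-12 and 1.96e-06, and 0.00421 and 0.0233 with an estimated correlation). The estimated correlation left 3 sets of a kept family and 5 lists, fry 12 and 7, and a mean log2 CPM of at least 3 gave 11 such sets and ended 4 list calls. Signs turned for Mir17hg in tail bud Δ18 (−0.0017 without wild-type replicate 3, up to 0.17 without replicate 2) and for Cdkn1a in the full knockout heart (−0.037 with the sex covariate, and −0.0438, −0.0114, −0.00775 and −0.0947 without wild-type replicates 2 and 3 and knockout replicates 1 and 3, up to 0.15 without knockout replicate 2). Neither passed. Of 6545 named-gene values under alternatives, 5822 kept direction and side of the threshold, 708 no longer passed and 9 newly did. Fewer libraries lower power, but with only the groups compared some heart and rest counts rose. The cause was not tested. Depth limits genes with few counts most.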

Other observations

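The list tests in genotypes other than the full knockout (288, of which 57 passed with camera's preset correlation) were chosen after other results were seen. Chance was not tested for them.

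Targets of p53 were lower as a list in Δ92 in all 3 tissues, with medians of −0.10, −0.13 and −0.09 over 16 genes in tail bud, heart and rest (camera adjusted p = 0.00398, 0.000217 and 1.52e-05; adjusted p = 0.359, 0.359 and 0.0674 with an estimated correlation). The cyclin gene Ccng1 passed in tail bud (−0.53 ± 0.10) and rest (−0.58 ± 0.07). The death receptor gene Eda2r passed in the rest (−0.91 ± 0.12, but 0.25 in the full knockout and −0.16 in Δ17,18,92). In heart 0 members passed (edgeR, with 2 at an unadjusted p under 0.05 and 0 with DESeq2). Sex moved with Δ92, since Y-linked genes were expressed by 0 of its 3 replicate numbers and 2 of 3 in wild type, and Eda2r is X-linked. With a sex covariate they were −0.47 for Ccng1 in tail bud (adjusted p = 0.0503) and −0.57 and −0.97 for Ccng1 and Eda2r in the rest (0.000465 and 9.24e-05). The list was not tested with it. TGF-β and BMP genes rose in the rest of the embryo of Δ17,18,92, with 10 of 15 higher (median 0.41, adjusted p = 4.63e-08; adjusted p = 0.0107 with an estimated correlation). Endothelial genes were higher there too, with 6 of 12 past the threshold (median 0.20, 7.29e-06; adjusted p = 0.180 with an estimated correlation). Among them were Pecam1 (0.44 ± 0.07), Tie1 (0.25 ± 0.06), Tek (0.31 ± 0.08) and Flt1 (0.25 ± 0.07). Without replicate 2 of the genotype the adjusted p values of Tie1, Tek and Flt1 were 0.236, 0.389 and 0.156. Heart markers moved with both lists, as 97% of 100 heart-enriched genes lay above 0 in these 2 libraries (median 0.60).

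Hox genes rose as a list in Δ19 tail bud, with 3 of 37 higher (median 0.14, adjusted p = 2.83e-05; adjusted p = 0.446 with an estimated correlation). They were Hoxb4 (0.46), Hoxb5 (0.42) and Hoxa5 (0.34), whose adjusted p values without Δ19 replicate 1 were 0.115, 0.126 and 0.181. In heart the same list was higher in Δ17,18 (median 0.94, 7.39e-07) and Δ92 (0.71, 9.4e-07), both with adjusted p = 0.788 with an estimated correlation and with 0 of 31 genes past the threshold (edgeR; 5 and 2 at an unadjusted p under 0.05, 0 with DESeq2). Tail bud and segmentation genes moved with it in the same hearts (0.79, 0.00247 and 0.51, 0.00298; adjusted p = 0.773 and 0.784 with an estimated correlation), with 0 of 18 past the threshold (4 and 0 unadjusted, 0 with DESeq2). Erythroid genes in Δ18 heart (median 1.66, 1.87e-09; adjusted p = 0.495 with an estimated correlation) and cardiomyocyte genes in the rest of the embryo of Δ92 (0.37, 9.45e-07; adjusted p = 0.590 with an estimated correlation) also had 0 members past it (1 and 5 unadjusted, 0 with DESeq2).

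Tail bud wild-type replicate 3 held Xist at 52.0 CPM together with Y-linked RNA, against 3.52 and 2117 in replicates 1 and 2.

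A comparison of 3 libraries with 3 has 10 splits, too few for a share under 0.05, and 1 of 10 gave as many in each case. The real counts and the highest of the other splits were 1776 and 0, 301 and 1, 22 and 0, 175 and 7, 61 and 1, 1414 and 0, and 947 and 1 in tail bud for the full knockout, Δ17, Δ18, Δ19, Δ92, Δ17,18 and Δ17,18,92. In heart they were 655 and 1, 93 and 1, 7 and 1, 68 and 0, 12 and 0, 187 and 1, and 316 and 7. In the rest they were 1167 and 1, 274 and 1, 63 and 0, 329 and 0, 103 and 0, and 778 and 0 without Δ17,18,92. The wild-type tissues gave 11611, 11524 and 5051 with 0 as the highest other, also among the splits that part every pair.

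For the family terms 1 of 41 splits, the real one, gave as many genes in each tissue. This is the smallest share 41 splits can give, not adjusted over terms and tissues. The highest others for miR-17, miR-18, miR-19 and miR-92 were 94, 1, 346 and 21 against 926, 55, 906 and 623 in tail bud. They were 2, 9, 542 and 65 against 604, 15, 732 and 264 in heart, and 9, 0, 1 and 0 against 1311, 131, 1154 and 907 in the rest. For departure from additivity 1 of 41 splits gave as many in tail bud (3 genes, highest other 1) and the rest (18 and 4). In heart 2 of 41 did (10 and 14). These splits also broke up the family effects, so chance stays open for departure. Chance was argued against for sets of a lost family (39 against 23, 1 of 61 splits, the smallest possible share). It was not excluded for sets of a kept family, with 43 of 61 splits at 7 or more and a highest other of 23, nor for the 12 fixed lists that shifted in the full knockout, with 27 of 61 and 18.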
